A study of Mus musculus with 30 samples.

How the data were processed

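Gene expression was measured by RNA sequencing in 30 mouse samples (male C57BL/6J mice per the labels) at 5 pathological stages. Libraries were made with a stranded mRNA kit, reads were trimmed with cutadapt 2.4 and aligned with STAR 2.7.2a to GRCm38 per the submitters' processing notes. The counting tool, the strand setting and the annotation release are not stated in those notes. The authors deposited 1 table of raw counts per Ensembl gene, and its values are whole numbers with a different total in each sample. Of its 55487 identifiers, 55227 (99.53%) matched GENCODE M21 on GRCm38 without the version, which gave symbols and positions, and 21379 had no count in any sample. Samples were grouped by the stage in their labels, and none was left out. The Y-linked gene Ddx3y had 926 to 2093 counts in each sample, against 0 to 97 for Xist.

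Total counts ran from 17725604 to 28023098 per sample. edgeR 4.0.16 in R 4.3.3 was run with TMM normalization (factors 0.892 to 1.057) and its default expression filter, which kept 17638 genes. A quasi-likelihood model with robust dispersion and 1 mean per stage was fitted to all 30 samples, so that groups share 1 estimate of the spread. The common dispersion was 0.0576, a biological coefficient of variation of 24%. Comparisons numbered 8, each two-sided, with Benjamini-Hochberg adjustment within the comparison and a call at an adjusted p under 0.05. CPM values use the same TMM factors. On simulated data with 200 changed genes per comparison, the test recovered 35.8% to 82.1% of 1.5-fold changes, 74.6% to 91.0% of 2-fold changes and 92.4% to 100% of 4-fold changes, with 2.2% to 6.8% of calls false.

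Gene lists numbered 43, with at least 5 tested members each, and covered the tissue's cell types, immune cells and pathways. Each was tested against all other genes with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison. Camera was repeated with a correlation estimated per list, and fry was run as a self-contained test. Members that rose or fell are counted after adjustment over all genes and, separately, over the list alone. A list score is the mean log2 CPM of its genes, with a prior count of 2. Principal components used the 2000 most variable genes.

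Named genes follow a rule. In each comparison these are the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 10 CPM in the higher group, up to 4 members with the smallest adjusted p from each list described, and members of the checkpoint and driver gene lists; where fewer are named, they are mostly taken from the top of the order. Predicted genes, pseudogenes and antigen receptor variable segments were left out of the ranking, which removed 0 to 175 genes per comparison. The comparisons, tests, lists and this rule were chosen before the data were examined.

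Alternatives were RLE and upper-quartile factors, no expression filter, DESeq2 1.42.0, limma-voom with sample weights, a fit of only the 2 groups compared, an adjusted p under 0.01, glmTreat against a fold of 1.5, the skeletal muscle score as a covariate, muscle genes removed, leaving out each sample in turn, and the number in the sample code as a replicate block. The salivary gland score as a covariate, both scores together, leave-one-out for the lists, and leaving out D01, B01 and C12 were added after the data were seen. In 50 random splits of the samples per comparison, called genes were counted again. The overlap of calls of hyperplasia and invasive carcinoma was set beside that of independent calls and 12 simulations of unchanged groups sharing normal samples. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.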

Results

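RNA was sequenced from 30 mouse samples of a chemically induced model of oral squamous cell carcinoma, in which 4-nitroquinoline-1-oxide (4NQO), a carcinogen that forms bulky DNA adducts, is given in drinking water. The labels sort the samples by pathological stage into 3 normal, 8 hyperplasia, 7 dysplasia, 6 carcinoma in situ and 6 invasive carcinoma samples. The protocol on every sample, the normal ones included, is 100 ug/mL of 4NQO for 10 weeks from 6 weeks of age, so the labels do not say whether the normal mice took the carcinogen. Total counts ran from 17725604 to 28023098 per sample, and 17638 of 55487 listed genes had enough counts to be tested. Each stage was compared with normal tissue and with the stage before it, and invasive carcinoma was also compared with hyperplasia, to follow the transcriptome from normal tissue to invasion. Group values are means ± SD in CPM, the count of a gene scaled to the library's total, and log2 fold changes carry ± 1 standard error. The p-values measure the spread between these samples, which the labels do not say come from separate animals, and intervals and floors cover counting error only. The sample code letter is D for normal, A for hyperplasia, B for dysplasia and C for both carcinoma stages. A batch that follows the letters therefore cannot be told apart from stage in any comparison but that of the carcinoma stages.

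Tissue make-up varied within every group. The largest component of variation, 33.3% of the variance, was led by the salivary secretory genes Bpifb2, Muc5b and Gp2. Its group means ran from -23.59 in normal tissue through -10.57, 0.06 and 11.38 to 14.45 in invasive carcinoma, with SDs within groups of 25.49 to 40.92. Component 2, 23.7% of the variance, was led by the inflammatory and barrier genes S100a9, S100a8, Sprr2d and Saa3, and its group means ran from -41.2 in normal tissue through -12.1, -5.63 and 17.5 to 25.8 in invasive carcinoma. The mean score of the skeletal muscle list was 10.3 ± 0.275 log2 CPM in normal tissue (n = 3), 9.97 ± 0.288 in hyperplasia (n = 8), 9.60 ± 0.330 in dysplasia (n = 7), 9.59 ± 0.293 in carcinoma in situ (n = 6) and 9.34 ± 0.417 in invasive carcinoma (n = 6). Mitochondrial transcripts took 11.6% ± 1.83 of the counts in normal tissue, 9.16% ± 1.16 in hyperplasia, 7.50% ± 0.733 in dysplasia, 6.90% ± 1.14 in carcinoma in situ and 6.59% ± 1.37 in invasive carcinoma.

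**Figure D1:**
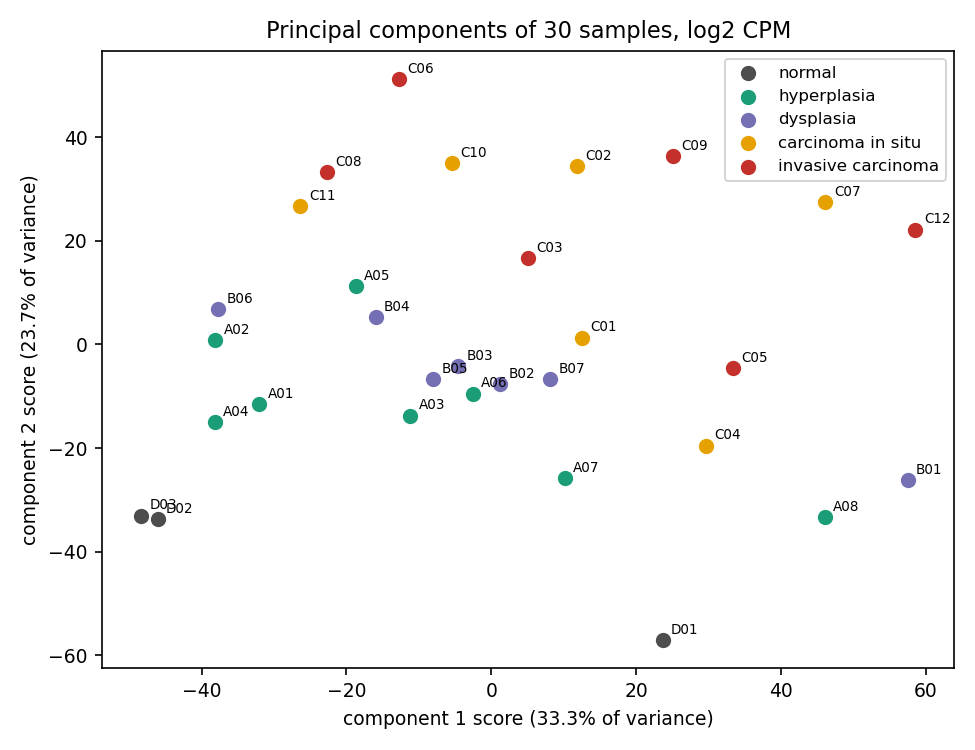
Principal components 1 (33.3% of variance, x axis) and 2 (23.7%, y axis) of log2 CPM over the 2000 most variable genes, where each point is 1 of the 30 samples, coloured by stage and marked with its code.

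Antigen presentation and interferon response transcripts were higher in hyperplasia (n = 8) than in normal tissue (n = 3). Nlrc5, the transcriptional activator of the MHC class I genes (GRCm38 chromosome 8, 94434356 to 94527272, ENSMUSG00000074151.13), rose from 10.1 ± 4.14 to 58.7 ± 7.37 CPM, a log2 fold change of 2.53 ± 0.25 (adjusted p = 2.6e-07). Tap1, which carries peptides to class I molecules, rose from 19.9 ± 5.23 to 77.2 ± 11.95 CPM, by 1.96 ± 0.25 (adjusted p = 1.8e-05), and for both genes all 8 hyperplasia samples lay above every normal sample. In the MHC class I list 15 of 16 tested members rose over all genes and 16 adjusted over the list alone (median 1.497, camera adjusted p = 5.9e-19), and the class II list gave 9 of 12 and 10 (median 1.02, 2.3e-10); both had an adjusted p of 0.145 with an estimated correlation. H2-Ab1, a class II chain, was 43.8 ± 5.64 CPM in normal tissue and 108 ± 14.9 in hyperplasia, a rise of 1.30 ± 0.22 (adjusted p = 2.2e-04, 8 of 8 samples above every normal sample). The type I interferon list rose in 19 of 25 members and in 22 adjusted over the list alone (median 1.33, camera adjusted p = 1.4e-15, 0.203 with an estimated correlation). In it Mx1, an antiviral GTPase, rose by 2.90 ± 0.51 (adjusted p = 3.4e-04, 8 of 8).

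NRF2 targets, p53 targets and cell cycle genes also rose in hyperplasia. Nqo1, a quinone reductase that NRF2 induces, went from 72.9 ± 4.61 to 296 ± 55.3 CPM (log2 2.02 ± 0.28, adjusted p = 3.0e-05), and Akr1b8, an aldo-keto reductase, from 7.08 ± 2.09 to 63.4 ± 15.9 (3.16 ± 0.44, 4.7e-05). Pmaip1, a p53 target that promotes apoptosis, rose from 0.826 ± 0.371 to 8.91 ± 0.828 CPM (3.42 ± 0.45, adjusted p = 1.9e-05). Mcm3, a subunit of the replicative helicase, rose from 9.34 ± 1.61 to 21.98 ± 2.98 CPM (1.23 ± 0.18, adjusted p = 4.2e-05). All 8 hyperplasia samples lay above every normal sample for each of these 4 genes. The NRF2 list rose in 17 of 25 members and 19 adjusted over the list alone (median 0.89, camera adjusted p = 5.9e-19, 0.145 with an estimated correlation). In the p53 target list 12 of 22 rose and 2 fell, and 13 and 2 adjusted over the list alone (median 0.36, camera adjusted p = 9.1e-06, 0.125 with an estimated correlation). In the cell cycle list 24 of 40 rose, and 32 adjusted over the list alone (median 0.49, camera adjusted p = 1.2e-14, 0.203 with an estimated correlation).

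Markers of regulatory T cells and dendritic cells were higher in hyperplasia. Foxp3, the regulator that defines regulatory T cells (GRCm38 chromosome X, 7573644 to 7595245, ENSMUSG00000039521.13), rose from 0.155 ± 0.0618 to 2.07 ± 0.583 CPM (log2 3.71 ± 0.41, adjusted p = 1.3e-06). The dendritic cell integrin Itgax rose from 1.71 ± 0.0880 to 7.66 ± 1.09 (2.16 ± 0.24, 1.3e-06), both genes in 8 of 8 samples above every normal sample. The regulatory T cell list rose in 8 of 11 members, with 8 rising and 1 falling adjusted over the list alone (median 2.13, camera adjusted p = 4.1e-05, 0.145 with an estimated correlation). Of 22 T cell genes 12 rose, 13 adjusted over the list alone (median 1.61, camera adjusted p = 1.8e-07, 0.145 with an estimated correlation), and of 17 dendritic and Langerhans cell genes 7 rose both ways (median 1.06, 3.1e-04, 0.203 with an estimated correlation). Icos, a costimulatory receptor, rose by 2.82 ± 0.44 (adjusted p = 1.3e-04, 8 of 8), and by 3.66 without normal sample D01. Cdkn2a, which encodes the p16 and ARF inhibitors of proliferation (GRCm38 chromosome 4, 89274471 to 89294653, ENSMUSG00000044303.6), rose from 0.168 ± 0.0525 to 3.14 ± 0.932 CPM (4.17 ± 0.59, 4.6e-05, 8 of 8). Trp53 rose by 0.39 ± 0.09 (adjusted p = 0.00543, 8 of 8), with an adjusted p of 0.078 without normal sample D02.

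Injury keratin and alarmin transcripts were higher in hyperplasia. Krt6b, a keratin of wounded epithelium, rose from 1305 ± 355 to 5823 ± 1803 CPM (log2 2.16 ± 0.26, adjusted p = 3.5e-06, 8 of 8 above every normal sample). In all, 8 of 21 injury keratins and alarmins rose, 9 adjusted over the list alone (median 0.88, camera adjusted p = 1.8e-04, 0.444 with an estimated correlation). The cornified envelope genes Sprr2e, Sprr2f and Sprr2d, near-identical paralogs that may share reads, rose by 9.07 ± 2.21, 8.91 ± 1.73 and 7.78 ± 1.70 in 8 of 8 samples (adjusted p = 0.00752, 0.00126 and 0.0034). The cornified envelope list median against normal tissue was 0.017, then 0.288, -0.283 and 0.062 in the later stages. Sprr2e and Sprr2f had 1 and 2 counts over the normal samples, and the exact 95% counting intervals of their log2 ratios of pooled counts were 6.85 to 14.64 and 7.12 to 12.02. S100a9, a neutrophil and keratinocyte alarmin (GRCm38 chromosome 3, 90692632 to 90695721, ENSMUSG00000056071.12), rose from 2.27 ± 1.51 to 154 ± 272 CPM (6.08 ± 1.51, adjusted p = 0.0084, 8 of 8). These increases were 8.07, 7.99, 6.57 and 4.77 without hyperplasia sample A05. Without normal sample D03 Sprr2e rose by 11.07, and without D01 S100a9 rose by 6.76. Without D02 the adjusted p was 0.0519 for Sprr2e and 0.0638 for S100a9, and limma-voom gave 0.26 for Sprr2e, 0.143 for Sprr2f, 0.239 for Sprr2d and 0.152 for S100a9.

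Oxidative phosphorylation and skeletal muscle transcripts were lower in hyperplasia. Of 13 salivary gland genes 0 were called (camera adjusted p = 0.81), but outside that list the salivary kallikrein Klk1 fell from 40.8 ± 32.5 to 0.396 ± 0.448 CPM (log2 -6.69 ± 1.45, adjusted p = 0.0033, 8 of 8 below every normal sample). Without normal sample D01 the value was -5.81, and without hyperplasia sample A08 -7.33. Slc4a1, the erythrocyte anion exchanger, fell by 7.22 ± 1.65 (adjusted p = 0.00472, 2 of 8 below every normal sample), a value set by normal sample D01, without which it was -0.56 (adjusted p = 0.916); it was -7.83 without either D02 or D03. Klk1b9, which may share reads with other Klk1b genes, fell by 6.53 ± 0.99 (adjusted p = 1.1e-04, 7 of 8). Its value was -8.03 without A08 and -2.88 without D03 (adjusted p = 0.0716). Oxidative phosphorylation transcripts were lower together (median -0.35), with 3 of 26 falling over all genes and 24 adjusted over the list alone (camera adjusted p = 1.1e-08, 0.444 with an estimated correlation). The skeletal muscle list (median -0.42) had 5 of 32 members falling and 1 rising, 8 and 1 adjusted over the list alone (camera adjusted p = 6.7e-05, 0.637 with an estimated correlation). Mb, the muscle oxygen carrier, fell by 0.75 ± 0.19 (adjusted p = 0.0104, 8 of 8), but its value was -0.61 without D02 (adjusted p = 0.10).

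The edgeR test called 1449 genes higher and 1070 lower in hyperplasia than in normal tissue, of which 554 and 208 changed at least 2-fold, and 5160 genes (29.3%) had an unadjusted p under 0.05. Without normal sample D02 the count was 926. The share of called genes that were higher was 57.5%, but 48.0% with RLE factors. Camera called 25 of 43 gene lists, and 0 with an estimated correlation.

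**Figure D2:**
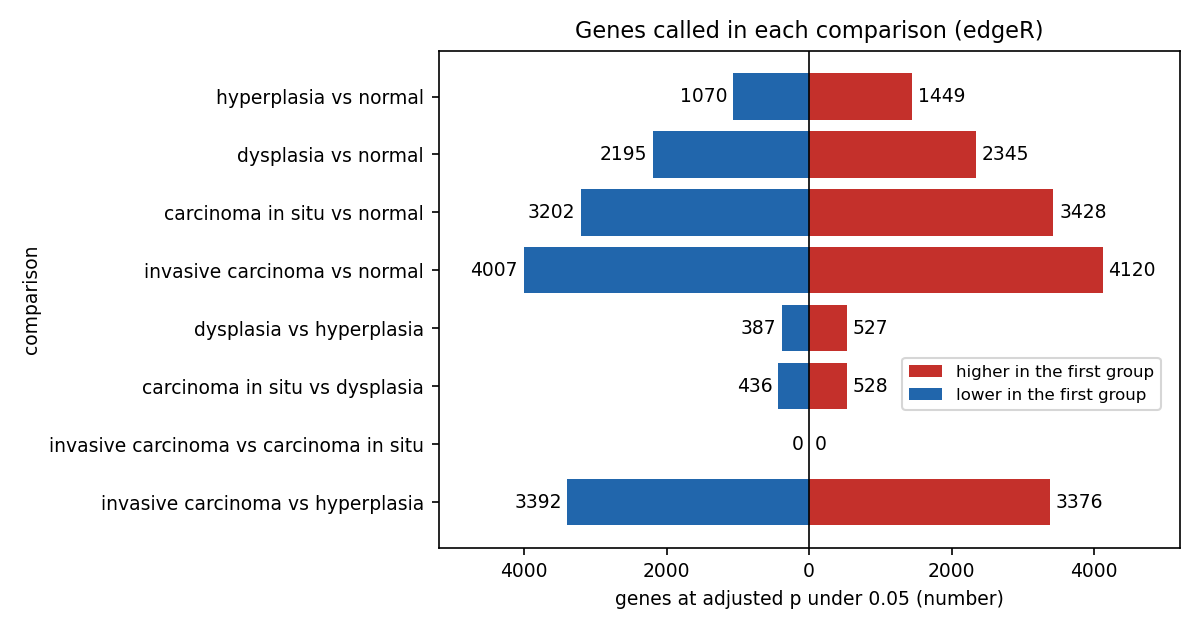
Number of genes with an adjusted p under 0.05 in edgeR (x axis, genes) for each of the 8 comparisons (y axis), with bars to the left for genes lower and to the right for genes higher in the first-named stage. Counts ran from 0 for invasive carcinoma against carcinoma in situ to 4007 lower and 4120 higher for invasive carcinoma against normal tissue.

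Dysplasia (n = 7) differed from normal tissue (n = 3) by higher injury keratin, NRF2 target and antigen presentation transcripts and by lower energy metabolism and muscle transcripts. Krt6b (GRCm38 chromosome 15, 101676023 to 101680287) rose from 1305 ± 355 to 7558 ± 1683 CPM (log2 2.53 ± 0.27, adjusted p = 2.0e-06), and Krt16, its wound-response partner, from 1264 ± 233 to 5078 ± 1505 (2.01 ± 0.30, 9.4e-05). Nfkbiz, an amplifier of IL-17 signalling, rose from 12.7 ± 3.19 to 69.1 ± 22.1 CPM (2.45 ± 0.32, adjusted p = 3.4e-05). Krt1, the keratin of cornifying epidermis, rose from 9.43 ± 3.01 to 191 ± 112 CPM (4.34 ± 0.72, adjusted p = 3.2e-04), and for these 4 genes all 7 dysplasia samples lay above every normal sample. The injury keratin and alarmin list rose in 11 of 21 members and 12 adjusted over the list alone (median 1.76, camera adjusted p = 2.1e-07, 0.46 with an estimated correlation), and the IL-17 and acute inflammatory cytokine list in 8 of 24 and 12 (median 2.50, 7.2e-04, 0.499 with an estimated correlation). Lipid barrier synthesis genes rose in 12 of 22 both ways (median 0.44, camera adjusted p = 2.2e-05, 0.46 with an estimated correlation).

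The NRF2 list again rose in 17 of 25 members, 20 adjusted over the list alone (median 0.90, camera adjusted p = 5.4e-14, 0.46 with an estimated correlation). Akr1b8 reached 70.5 ± 14.5 CPM in dysplasia (log2 3.31 ± 0.45, adjusted p = 6.4e-05, 7 of 7). MHC class I genes rose in 12 of 16 both ways (median 0.87, camera adjusted p = 1.2e-06) and class II genes in 9 of 12 and 10 adjusted over the list alone (median 0.95, 2.0e-06), each with an adjusted p of 0.46 with an estimated correlation. Nlrc5 rose by 2.03 ± 0.24 (adjusted p = 7.9e-06, 7 of 7) and Foxp3 by 2.33 ± 0.42 (5.0e-04, 7 of 7). Of 40 cell cycle genes 10 rose, 12 adjusted over the list alone (median 0.33, camera adjusted p = 1.4e-05, 0.516 with an estimated correlation). In contrast to hyperplasia, the type I interferon list had 2 of 25 members called and was itself not called (camera adjusted p = 0.834).

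Oxidative phosphorylation genes fell in 25 of 26 members, 26 adjusted over the list alone (median -0.52, camera adjusted p = 9.3e-12, 0.46 with an estimated correlation). Ndufb5, a complex I subunit, fell from 219 ± 41.1 to 137 ± 15.5 CPM (log2 -0.67 ± 0.13, adjusted p = 8.2e-04, 7 of 7 below every normal sample). Of 11 mitochondrially encoded genes 7 fell, 10 adjusted over the list alone (median -0.81, camera adjusted p = 9.7e-06, 0.46 with an estimated correlation). The skeletal muscle list fell with them in 24 of 32 members, 28 adjusted over the list alone (median -0.69, camera adjusted p = 8.0e-10, 0.495 with an estimated correlation). Acta1, skeletal actin, fell by 0.85 ± 0.21 (adjusted p = 0.00463, 7 of 7), but its value was -0.70 without normal sample D02 (adjusted p = 0.0567).

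Among the largest changes in dysplasia, Sprr2e, Sprr2f and Sprr2d rose by log2 10.34 ± 2.12, 9.98 ± 1.69 and 9.47 ± 1.80 (adjusted p = 0.00162, 3.7e-04 and 9.2e-04, 7 of 7; counting intervals 8.25 to 16.04 for Sprr2e and 8.33 to 13.23 for Sprr2f), with Sprr2e at 12.36 without normal sample D03. S100a9 reached 478 ± 207 CPM (7.72 ± 1.63, adjusted p = 0.00196, 7 of 7), and rose by 8.42 without D01. Klk6, a trypsin-like protease of squamous epithelium (GRCm38 chromosome 7, 43824499 to 43832030), rose from 0.114 ± 0.0608 to 21.9 ± 28.04 CPM (7.47 ± 1.51, adjusted p = 0.0015, 7 of 7), and by 6.52 without dysplasia sample B06. With limma-voom the adjusted p was 0.0838 for Sprr2e and 0.066 for Klk6. Klk1b9 fell by 6.23 ± 1.02 (adjusted p = 2.8e-04, 6 of 7). Its value was -8.20 without dysplasia sample B05 and -2.56 without D03 (adjusted p = 0.0851). Fam107a, a glucocorticoid-responsive actin regulator, fell from 11.4 ± 6.5 to 2.79 ± 0.904 CPM (-2.03 ± 0.40, adjusted p = 0.00115, 7 of 7). Lyg1, a goose-type lysozyme (GRCm38 chromosome 1, 37946736 to 37957759), fell from 902 ± 67.6 to 251 ± 114 (-1.84 ± 0.48, 0.00758, 7 of 7).

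In all, edgeR called 2345 genes higher and 2195 lower in dysplasia than in normal tissue, 506 and 204 of them at least 2-fold, with 6748 at an unadjusted p under 0.05. Without normal sample D02 the count was 1282, and with the skeletal muscle score as a covariate 768. The share of called genes that were higher was 51.7%, but 47.1% with RLE and 47.7% with upper-quartile factors. Camera called 24 of 43 lists here, and 0 with an estimated correlation.

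Carcinoma in situ (n = 6) exceeded normal tissue (n = 3) in inflammatory cytokine and alarmin transcripts. Cxcl1, a neutrophil attractant (GRCm38 chromosome 5, 90891241 to 90893115), rose from 0.117 ± 0.0547 to 7.40 ± 7.001 CPM (log2 5.90 ± 1.09, adjusted p = 3.0e-04), and Zc3h12a, an RNase that limits inflammatory transcripts, from 16.2 ± 2.32 to 111 ± 34.5 (2.77 ± 0.35, 8.4e-06). Cdkn2a rose from 0.168 ± 0.0525 to 10.3 ± 6.02 CPM (5.88 ± 0.61, adjusted p = 5.7e-07). Hif1a, the oxygen-regulated transcription factor, rose from 83.7 ± 7.75 to 341 ± 104 CPM (2.03 ± 0.31, adjusted p = 4.2e-05), and for these 4 genes all 6 carcinomas in situ lay above every normal sample. The IL-17 and acute inflammatory cytokine list rose in 21 of 24 members, 22 adjusted over the list alone (median 4.97, camera adjusted p = 9.2e-07, 0.329 with an estimated correlation). Neutrophil genes rose in 12 of 18, 13 adjusted over the list alone (median 3.53, camera adjusted p = 0.00117, 0.421 with an estimated correlation), and injury keratins and alarmins in 17 of 21 both ways (median 1.82, 7.3e-07, 0.329 with an estimated correlation).

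Matrix proteases and basal keratinocyte genes were also higher in carcinoma in situ. Mmp12, the macrophage elastase, rose from 0.464 ± 0.258 to 6.35 ± 3.39 CPM (log2 3.74 ± 0.50, adjusted p = 1.1e-05), and Plau, the urokinase that activates plasminogen, from 20.4 ± 0.766 to 73.3 ± 25.8 (1.84 ± 0.29, 6.3e-05), each in 6 of 6 samples. The invasion protease and laminin receptor list rose in 15 of 21 members, 16 adjusted over the list alone (median 1.24, camera adjusted p = 1.6e-04, 0.384 with an estimated correlation). Basal keratinocyte genes rose in 11 of 15 and fell in 1 both ways (median 0.87, camera adjusted p = 1.6e-04, 0.371 with an estimated correlation), with Krt14 going from 1542 ± 212 to 4531 ± 1255 CPM (1.56 ± 0.30, adjusted p = 4.1e-04, 6 of 6). The NRF2 list rose in 20 of 25, 21 adjusted over the list alone (median 1.37, camera adjusted p = 2.6e-13, 0.329 with an estimated correlation), led by the glutathione transferase Gsta4 at 996 ± 367 against 232 ± 28.5 CPM (2.10 ± 0.25, adjusted p = 3.2e-06, 6 of 6). Cell cycle genes rose in 29 of 40, 33 adjusted over the list alone (median 0.56, camera adjusted p = 2.1e-08, 0.384 with an estimated correlation), and class II genes in 11 of 12 both ways (median 1.22, 2.1e-07, 0.329 with an estimated correlation). In the type I interferon list 3 of 25 members fell, and the list was not called.

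Transcripts of muscle, nerve and vessels were lower in carcinoma in situ. The skeletal muscle list fell in 26 of 32 members, 27 adjusted over the list alone (median -0.77, camera adjusted p = 5.1e-08, 0.421 with an estimated correlation). The actin-binding Xirp1 fell from 168 ± 14.95 to 78.4 ± 16.8 CPM (log2 -1.10 ± 0.22, adjusted p = 4.6e-04, 6 of 6 below every normal sample). Oxidative phosphorylation genes fell beside it in 26 of 26 both ways (median -0.55, camera adjusted p = 3.8e-09, 0.384 with an estimated correlation). Mbp, a myelin protein, fell from 160 ± 34.2 to 75.3 ± 13.9 CPM (-1.08 ± 0.16, adjusted p = 4.0e-05, 6 of 6), within a nerve and Schwann cell list in which 9 of 13 fell and 1 rose both ways (median -1.08, camera adjusted p = 7.0e-05, 0.329 with an estimated correlation). Endothelial genes fell in 11 of 15, with 12 falling and 1 rising adjusted over the list alone (median -0.47, camera adjusted p = 2.1e-04, 0.396 with an estimated correlation). The endothelial adhesion molecule Pecam1 (GRCm38 chromosome 11, 106654217 to 106750628) fell by 0.60 ± 0.13 (adjusted p = 0.00132, 6 of 6).

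The largest fitted increases in carcinoma in situ were Sprr2e (log2 10.51 ± 2.12, adjusted p = 6.9e-04), Saa3 (10.18 ± 2.06, 6.9e-04) and Sprr2f (10.03 ± 1.70, 1.5e-04), followed by Sprr2d and S100a9, in 6 of 6 samples. Their order rests on 1, 3 and 2 counts over the normal samples, with counting intervals of 8.44 to 16.23, 8.79 to 12.62 and 8.39 to 13.29. Saa3, an acute phase protein (GRCm38 chromosome 7, 46711998 to 46715700, ENSMUSG00000040026.8), was 0.0563 ± 0.0975 CPM in normal tissue and 65.6 ± 72.6 in carcinoma in situ; it rose by 13.55 without normal sample D02, 9.55 without D03 and 9.49 without carcinoma in situ sample C07. S100a9 reached 1166 ± 745 CPM, a rise of 9.01 ± 1.73 (adjusted p = 4.4e-04), and of 9.71 without D01. With limma-voom the adjusted p was 0.0797 for Sprr2e and 0.189 for Saa3. Klk1b9 fell by 6.93 ± 1.13 (adjusted p = 1.0e-04, 6 of 6), with -3.27 without D03. Lyg1 fell from 902 ± 67.6 to 133 ± 83.9 CPM (-2.76 ± 0.50, adjusted p = 2.8e-04, 6 of 6).

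The test in edgeR called 3428 genes higher and 3202 lower in carcinoma in situ than in normal tissue, 996 and 586 of them at least 2-fold, with 8214 at an unadjusted p under 0.05. Without normal sample D02 the count was 4238, and with the skeletal muscle score as a covariate 2023. The share that was higher was 51.7%, but 48.4% with RLE factors. Among 43 lists camera called 27, and 0 with an estimated correlation.

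Invasive carcinoma (n = 6) exceeded normal tissue (n = 3) in inflammatory cytokine, injury keratin and cell cycle transcripts. Nfkbiz rose from 12.7 ± 3.19 to 111 ± 15.6 CPM (log2 3.13 ± 0.34, adjusted p = 5.8e-07) and Cxcl1 from 0.117 ± 0.0547 to 11.5 ± 8.92 (6.53 ± 1.09, 6.3e-05). Krt6b reached 9442 ± 1806 CPM (2.86 ± 0.28, adjusted p = 1.1e-07) and Krt14, a basal keratin, 6564 ± 2701 (2.09 ± 0.31, 1.7e-05). Hif1a reached 470 ± 223 CPM (2.49 ± 0.32, adjusted p = 3.2e-06), and in all 5 genes 6 of 6 carcinomas lay above every normal sample. The IL-17 and acute inflammatory cytokine list rose in 23 of 24 members both ways (median 5.46, camera adjusted p = 4.6e-07), and injury keratins and alarmins in 17 of 21 both ways (median 2.38, 3.5e-08), each with an adjusted p of 0.33 with an estimated correlation. Cell cycle genes rose in 31 of 40, 35 adjusted over the list alone (median 0.62, camera adjusted p = 2.0e-09, 0.33 with an estimated correlation), with the helicase subunit Mcm5 at 41.4 ± 9.74 against 11.2 ± 2.11 CPM (1.88 ± 0.22, adjusted p = 1.5e-06, 6 of 6).

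Invasion proteases and laminin receptors rose in 14 of 21 members and fell in 2, 16 and 2 adjusted over the list alone (median 1.33, camera adjusted p = 0.00102, 0.457 with an estimated correlation). Basal keratinocyte genes rose in 11 of 15 and fell in 1 both ways (median 0.96, camera adjusted p = 4.5e-04, 0.33 with an estimated correlation), and neutrophil genes rose in 13 of 18 both ways (median 3.95, 4.9e-04, 0.417 with an estimated correlation). NRF2 targets rose in 19 of 25 and fell in 1, 20 and 1 adjusted over the list alone (median 1.04, camera adjusted p = 3.1e-09, 0.33 with an estimated correlation). Ribosomal protein genes rose in 19 of 32, 23 adjusted over the list alone (median 0.35, camera adjusted p = 4.1e-05, 0.531 with an estimated correlation). Cdkn2a was 6.79 ± 1.16 CPM, a rise of 5.28 ± 0.60 (adjusted p = 1.2e-06, 6 of 6), and Trp53 rose by 0.65 ± 0.10 (1.7e-05, 6 of 6). Isg15, an interferon-induced ubiquitin-like protein, was below normal tissue at 7.09 ± 3.69 against 21.3 ± 2.55 CPM, a fall of 1.58 ± 0.44 (adjusted p = 0.00524, 6 of 6). In the type I interferon list 4 of 25 members fell, 2 adjusted over the list alone (median -0.43, camera adjusted p = 0.0344, 0.695 with an estimated correlation). That list call was lost without normal sample D03 (adjusted p = 0.124) and without invasive carcinoma samples C06 (0.0657), C09 (0.0735) or C12 (0.0976), and with the skeletal muscle score as a covariate the median turned to 0.24 (0.973).

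The skeletal muscle list fell in 29 of 32 members both ways (median -0.91, camera adjusted p = 2.0e-09, 0.359 with an estimated correlation). Its member Tcap, a sarcomere protein, went from 1197 ± 342 to 484 ± 150 CPM (log2 -1.31 ± 0.22, adjusted p = 5.2e-05, 6 of 6 below every normal sample). Oxidative phosphorylation genes fell with it in 25 of 26, 26 adjusted over the list alone (median -0.65, camera adjusted p = 2.0e-09, 0.359 with an estimated correlation). Sdhc, a subunit of succinate dehydrogenase, fell from 324 ± 56.1 to 190 ± 36.4 CPM (-0.77 ± 0.15, adjusted p = 1.7e-04, 6 of 6). Endothelial genes fell in 14 of 15 both ways (median -0.75, camera adjusted p = 1.1e-05, 0.33 with an estimated correlation), with Pecam1 at 56.7 ± 8.72 against 103 ± 6.52 CPM (-0.86 ± 0.13, adjusted p = 2.5e-05, 6 of 6). Hair-type and papilla keratins fell in 16 of 24 and rose in 2, 17 and 2 adjusted over the list alone (median -1.22, camera adjusted p = 5.6e-04, 0.513 with an estimated correlation).

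Csn1s1, a milk casein (GRCm38 chromosome 5, 87666208 to 87682578, ENSMUSG00000070702.9), had no counts in the 3 normal samples. Against a floor of 3 counts over that group's total, or 0.0509 CPM, it was at least 433-fold higher in invasive carcinoma, at 22.01 CPM on average and 1.23 to 75.4 across samples (adjusted p = 3.2e-04, 6 of 6). Without invasive carcinoma sample C12 it was at least 223-fold higher, and the fitted log2 value of 11.95 ± 2.34 was 10.997. With list members at 0 in normal tissue set to that floor, the IL-17 list median was 2.22 in dysplasia, 4.69 in carcinoma in situ and 4.98 in invasive carcinoma, that of injury keratins 1.49 in dysplasia and that of neutrophils 3.45 in carcinoma in situ. Sprr2e rose by 11.73 ± 2.08 (adjusted p = 1.2e-04, 6 of 6), and by 13.75 without D03. Sprr2f rose by 11.35 ± 1.68 (2.3e-05), with counting intervals of 9.72 to 17.5 for Sprr2e and 9.77 to 14.67 for Sprr2f. Sprr2d rose by 10.69 ± 1.88 (1.1e-04) and S100a9 by 10.04 ± 1.79 (1.2e-04), each in 6 of 6, and S100a9 by 10.74 without D01. Klk1b9 fell by 8.91 ± 1.34 (adjusted p = 2.4e-05, 6 of 6), with -5.24 without D03 and -9.52 without C12.

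Overall edgeR called 4120 genes higher and 4007 lower in invasive carcinoma than in normal tissue, 1160 and 1002 of them at least 2-fold, with 9325 at an unadjusted p under 0.05. With the skeletal muscle score as a covariate the count was 1434, below the 2023 of carcinoma in situ. The share that was higher was 50.7%, but 49.0% with RLE and 49.3% with upper-quartile factors. Camera called 29 of the 43 lists, and 0 with an estimated correlation. Hyperplasia and invasive carcinoma shared 1123 genes called higher and 895 called lower against the same normal samples, with 9 called in opposite directions. Independent calls would share 338.5 and 243.1, but the normal samples are shared. Log2 values had r = 0.783 and covariance 0.485, against means of 0.722 and 0.101 for simulated unchanged groups. With few calls to share, their 0 shared calls cannot size the effect of common normal samples. Shared calls numbered 755 without normal sample D02 and 744 with the muscle covariate.

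**Figure D3:**
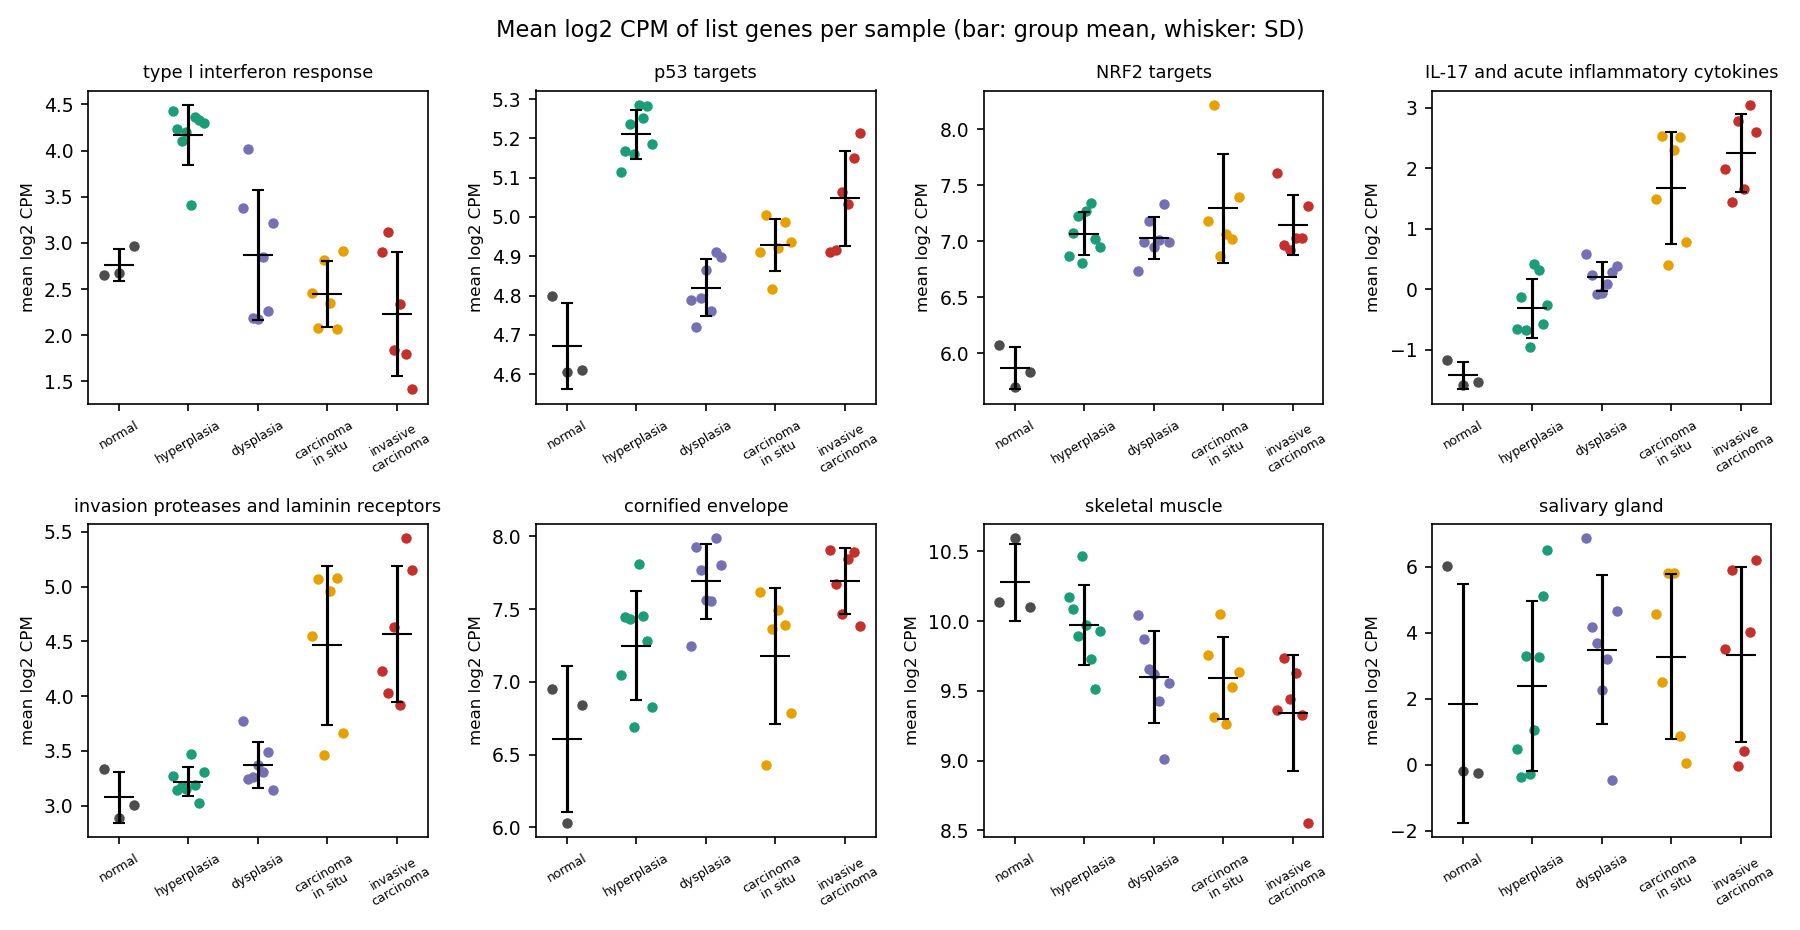
Mean log2 CPM over the genes of 8 fixed lists (y axis) in each stage (x axis), where points are samples, bars group means and whiskers 1 SD. The type I interferon mean is 2.76 in normal tissue, 4.17 in hyperplasia, 2.87 in dysplasia, 2.45 in carcinoma in situ and 2.23 in invasive carcinoma.

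Type I interferon and p53 target transcripts were lower in dysplasia (n = 7) than in hyperplasia (n = 8). Isg15 (GRCm38 chromosome 4, 156199424 to 156200818, ENSMUSG00000035692.7) fell from 52.4 ± 13.6 to 16.1 ± 12.8 CPM, a log2 fold change of -1.71 ± 0.34 (adjusted p = 0.00342). Irf7, the transcription factor that sustains interferon responses, fell from 35.0 ± 7.51 to 13.5 ± 7.20 (-1.37 ± 0.26, 0.00192), both in 6 of 7 samples below every hyperplasia sample. Trp53inp1, a stress-response target of p53 (GRCm38 chromosome 4, 11156431 to 11174379), fell from 90.7 ± 12.4 to 46.1 ± 6.82 CPM (-0.98 ± 0.13, adjusted p = 2.4e-05). Polk, a translesion DNA polymerase, fell from 12.3 ± 1.29 to 7.85 ± 0.221 (-0.65 ± 0.10, 1.6e-04), both in 7 of 7. In the interferon list 20 of 25 members fell and 24 adjusted over the list alone (median -1.26, camera adjusted p = 5.9e-32, 0.12 with an estimated correlation). The list score lay below every hyperplasia sample in 6 of 7. In the p53 target list 12 of 22 fell, with 13 falling and 1 rising adjusted over the list alone (median -0.41, camera adjusted p = 1.0e-10), a call that held at 0.00285 with an estimated correlation and in 7 of 7 samples. MHC class I genes fell in 7 of 16, 13 adjusted over the list alone (median -0.51, camera adjusted p = 7.3e-11, 0.398 with an estimated correlation), with Tap1 at 41.8 ± 16.6 against 77.2 ± 11.95 CPM (-0.88 ± 0.17, adjusted p = 0.00283, 6 of 7).

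Regulatory T cell and other immune cell markers were also lower in dysplasia. Foxp3 fell from 2.07 ± 0.583 to 0.795 ± 0.206 CPM (log2 -1.38 ± 0.23, adjusted p = 4.8e-04, 7 of 7 below every hyperplasia sample), and the receptor Tnfrsf18 from 4.53 ± 0.476 to 2.17 ± 0.346 (-1.06 ± 0.18, 4.8e-04, 7 of 7). Of 11 regulatory T cell genes 4 fell, with 7 falling and 1 rising adjusted over the list alone (median -0.70, camera adjusted p = 2.8e-05, 0.294 with an estimated correlation). Beside it the lists of T cells (0 of 22 fell, median -0.33), cytotoxic lymphocytes (1 of 12, -0.44) and macrophages and monocytes (2 of 22, -0.29) were lower, with camera adjusted p = 0.00102, 0.0113 and 1.2e-04, and p = 0.398, 0.449 and 0.398 with an estimated correlation. Of 22 checkpoint genes 3 fell, 5 adjusted over the list alone (median -0.23, camera adjusted p = 7.3e-04, 0.398 with an estimated correlation), among them Lgals9, a ligand of TIM-3, by 1.05 ± 0.16 (adjusted p = 2.5e-04, 6 of 7). In the cell cycle list 3 of 40 fell both ways (median -0.20, camera adjusted p = 1.9e-05, 0.522 with an estimated correlation).

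Epithelial differentiation and stress transcripts were higher in dysplasia than in hyperplasia. Krt1 (GRCm38 chromosome 15, 101845426 to 101850794) rose from 41.4 ± 28.4 to 191 ± 112 CPM (log2 2.21 ± 0.43, adjusted p = 0.00268, 6 of 7 above every hyperplasia sample). Defb3, an epithelial antimicrobial peptide (GRCm38 chromosome 8, 19293360 to 19295291), rose from 21.4 ± 24.4 to 123 ± 45.7 (2.53 ± 0.52, 0.00489, 6 of 7), or 3.18 without hyperplasia sample A05. Suprabasal differentiation genes rose in 3 of 23 both ways (median 0.25, camera adjusted p = 1.7e-05, 0.398 with an estimated correlation), and injury keratins and alarmins in 2 of 21, 5 adjusted over the list alone (median 0.38, 7.8e-06, 0.398 with an estimated correlation). Hspa1b, an inducible heat shock protein, rose from 70.8 ± 10.5 to 141 ± 23.9 CPM (0.998 ± 0.13, adjusted p = 1.8e-05, 7 of 7). Over all genes 6 of 22 immediate early and stress genes rose, with 6 rising and 1 falling adjusted over the list alone (median 0.22, camera adjusted p = 9.4e-04, 0.398 with an estimated correlation).

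The most separated genes between these stages fell in dysplasia. Cpt1c, a neuron-type carnitine palmitoyltransferase that p53 can induce (GRCm38 chromosome 7, 44959372 to 44974851, ENSMUSG00000007783.10), went from 21.98 ± 2.60 to 7.59 ± 0.599 CPM (log2 -1.53 ± 0.10, adjusted p = 9.0e-11). Mcam, a vascular adhesion molecule (GRCm38 chromosome 9, 44134469 to 44142727), went from 61.9 ± 3.70 to 27 ± 4.83 (-1.20 ± 0.10, 3.5e-09), and Igsf9b, an adhesion molecule of inhibitory synapses (GRCm38 chromosome 9, 27299204 to 27357546), from 10.5 ± 1.44 to 3.40 ± 0.481 (-1.63 ± 0.20, 5.1e-06). All 3 fell in 7 of 7 samples. Apol9a and Apol9b, interferon-induced paralogs that may share reads, fell by 1.90 ± 0.34 and 1.80 ± 0.31 (adjusted p = 0.00142 and 9.3e-04, 6 of 7 each). Of 32 skeletal muscle genes 4 fell, 5 adjusted over the list alone (median -0.26, camera adjusted p = 7.0e-06, 0.522 with an estimated correlation). With their own score as a covariate the median of 0.069 is uninformative. Klk1 and Krt42 gave the largest increases. Klk1 rose by 5.48 ± 1.32 (adjusted p = 0.0155, 2 of 7), by 6.13 without hyperplasia sample A08, and was 1.31 higher without dysplasia sample B05 (adjusted p = 0.443). Krt42, a keratin paralog, rose by 3.11 ± 0.70 (adjusted p = 0.0094, 5 of 7), and by 1.90 without dysplasia sample B06 (adjusted p = 0.0671).

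The edgeR test called 527 genes higher and 387 lower in dysplasia than in hyperplasia, 50 and 89 of them at least 2-fold, with 3696 at an unadjusted p under 0.05. The count was 571 without hyperplasia sample A01, 507 without A04, 543, 518 and 522 without dysplasia samples B03, B04 and B06, and 1486 without B01, and with the skeletal muscle score as a covariate 589. The share that was higher was 57.7%, but 40.9% with upper-quartile factors. Camera called 30 of 43 lists, and 1 with an estimated correlation.

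Carcinoma in situ (n = 6) exceeded dysplasia (n = 7) in inflammatory cytokine and matrix remodelling transcripts. Il1b, the pyrogenic cytokine (GRCm38 chromosome 2, 129364570 to 129371139), rose from 2.86 ± 1.18 to 19.4 ± 15.4 CPM (log2 2.76 ± 0.52, adjusted p = 0.00832). Inhba, an activin subunit (GRCm38 chromosome 13, 16011851 to 16031621), rose from 3.48 ± 0.710 to 18.6 ± 11.7 (2.42 ± 0.42, 0.00666). In each of these genes 5 of 6 samples lay above every dysplasia sample. Pdpn, a mucin-type glycoprotein of invasive fronts and lymphatic vessels, rose from 9.79 ± 0.946 to 17.7 ± 4.47 CPM (0.86 ± 0.14, adjusted p = 0.00408, 6 of 6). The IL-17 and acute inflammatory cytokine list rose in 13 of 24 members and 16 adjusted over the list alone (median 1.85), and the invasion protease and laminin receptor list in 11 of 21 and 17 (median 0.87). Both had a camera adjusted p of 5.0e-09, and of 0.426 with an estimated correlation. Cxcl1 rose from 0.714 ± 0.344 to 7.40 ± 7.001 CPM (3.35 ± 0.59, adjusted p = 0.00709, 5 of 6), and Mmp12 from 2.03 ± 0.427 to 6.35 ± 3.39 (1.65 ± 0.30, 0.00832, 5 of 6).

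Saa3 gave the largest increase, from 2.04 ± 1.78 to 65.6 ± 72.6 CPM (log2 4.99 ± 0.90, adjusted p = 0.00832, 4 of 6), and 4.29 without carcinoma in situ sample C07. Mmp13, an interstitial collagenase (GRCm38 chromosome 9, 7272514 to 7283331), rose by 3.67 ± 0.83 (adjusted p = 0.0168, 4 of 6) and by 4.47 without dysplasia sample B01, while its adjusted p was 0.0506 without C07. Neutrophil genes rose in 4 of 18, 6 adjusted over the list alone (median 1.32, camera adjusted p = 1.8e-05), and macrophage and monocyte genes in 3 of 22, 10 adjusted over the list alone (median 0.39, 1.1e-04), each with an adjusted p of 0.426 with an estimated correlation. Ribosomal protein genes were higher as a group (median 0.31), with 1 of 32 called over all genes and 32 adjusted over the list alone (camera adjusted p = 8.1e-14, 0.426 with an estimated correlation). Cdkn2a rose by 1.82 ± 0.31 (adjusted p = 0.00496, 4 of 6) and its neighbour Cdkn2b, which encodes p15, by 0.57 ± 0.10 (0.00707, 6 of 6). In the hypoxia and glycolysis list 2 of 22 rose, 4 adjusted over the list alone (median 0.27, camera adjusted p = 2.4e-04, 0.426 with an estimated correlation). Its member Slc2a1, a glucose transporter, rose by 1.23 ± 0.28 (adjusted p = 0.0161, 6 of 6) and by 0.95 without carcinoma in situ sample C02 (adjusted p = 0.0588).

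Cornified envelope and hair-type keratin transcripts were lower in carcinoma in situ than in dysplasia. Tchh, a hair and papilla sheath protein (GRCm38 chromosome 3, 93442330 to 93449077), fell from 2190 ± 633 to 728 ± 397 CPM (log2 -1.59 ± 0.34, adjusted p = 0.0117, 5 of 6 below every dysplasia sample). Flg, the filament-aggregating protein of cornified cells, fell by 1.60 ± 0.40 (adjusted p = 0.0248, 5 of 6), with an adjusted p of 0.0505 without B03, 0.0624 without C02, 0.0691 without C07 and 0.0666 without C10. Rptn, a cornified envelope protein, fell from 5636 ± 1501 to 2834 ± 1192 CPM (-0.99 ± 0.23, adjusted p = 0.0157, 4 of 6), with an adjusted p of 0.0527 without C07. The cornified envelope list fell in 4 of 27 members, 12 adjusted over the list alone (median -0.49, camera adjusted p = 9.2e-07), and the hair-type and papilla keratins in 4 of 24, 8 adjusted over the list alone (median -0.64, 1.1e-06), each with an adjusted p of 0.426 with an estimated correlation.

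In all, edgeR called 528 genes higher and 436 lower in carcinoma in situ than in dysplasia, 146 and 24 of them at least 2-fold, with 4112 at an unadjusted p under 0.05. The count was 164 without carcinoma in situ sample C07, 222 without C10, 272 without C02 and 2201 without C04, and 345 to 640 without any 1 of dysplasia samples B02 to B07. With the skeletal muscle score as a covariate it was 1886. The share that was higher was 54.8%, but 67.8% with upper-quartile factors. Among the 43 lists camera called 24, and 0 with an estimated correlation.

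**Figure D4:**
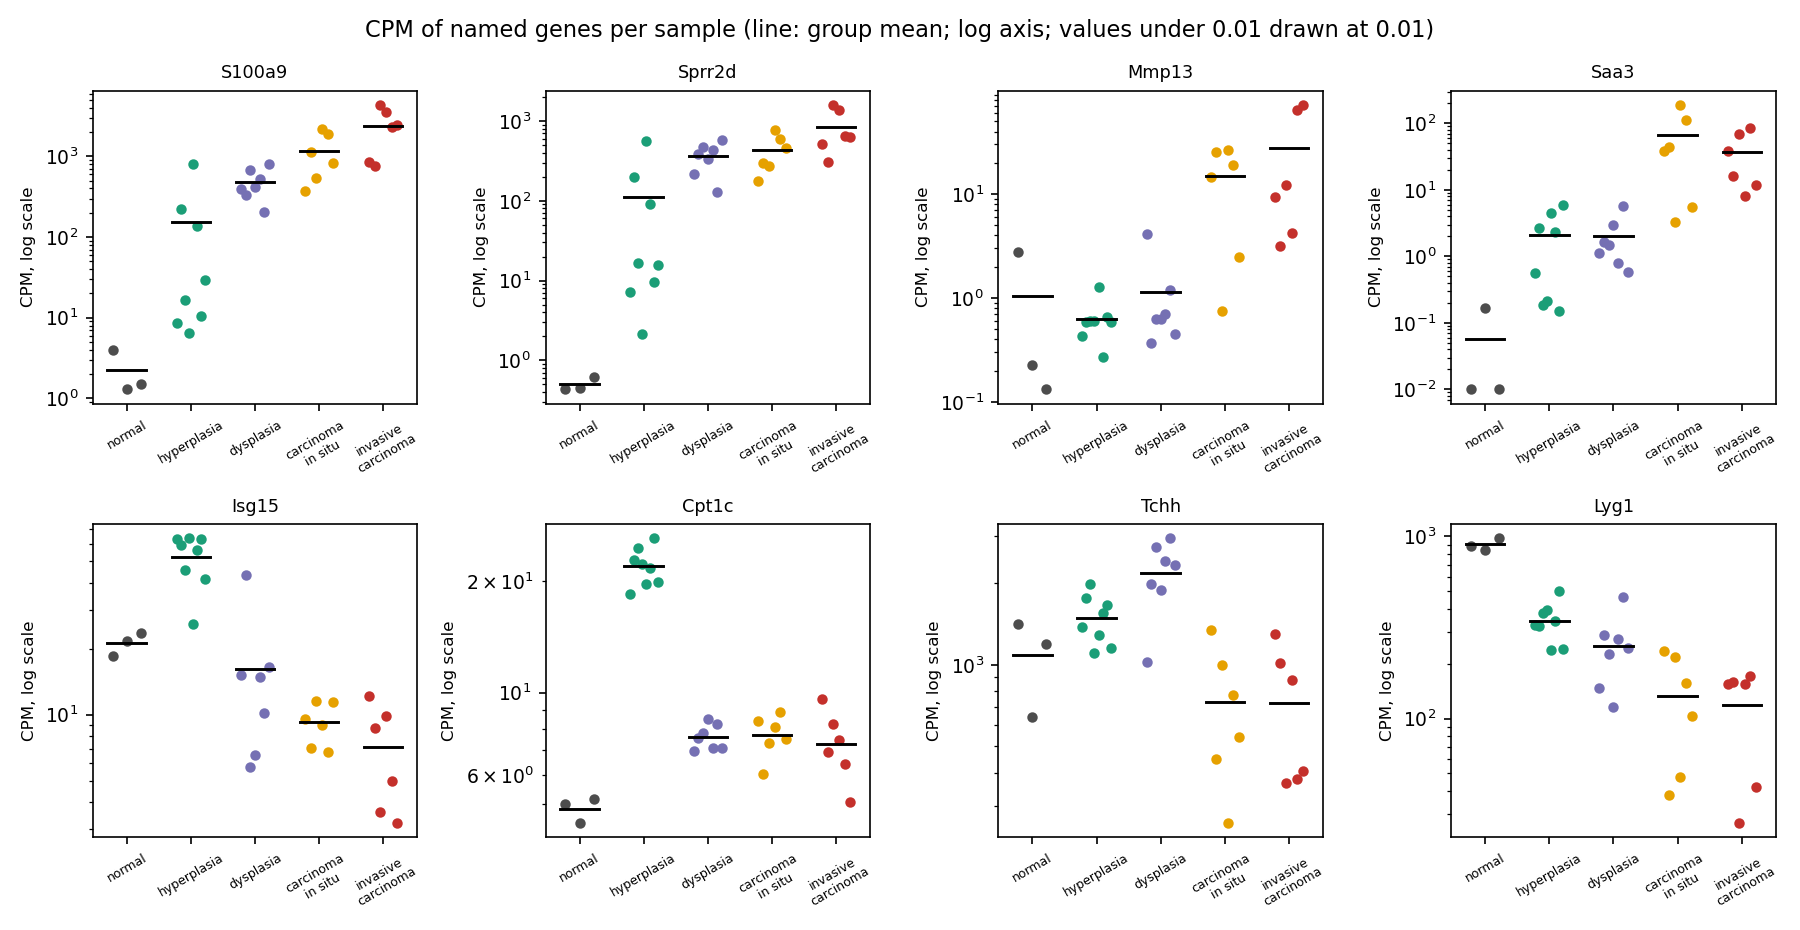
CPM on a log axis (y) of S100a9, Sprr2d, Mmp13, Saa3, Isg15, Cpt1c, Tchh and Lyg1 in each stage (x), where points are samples, lines group means, and values under 0.01 are drawn at 0.01. Mean S100a9 is 2.27 CPM in normal tissue and 2380 in invasive carcinoma, and mean Cpt1c 21.98 in hyperplasia and 7.59 in dysplasia.

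Invasive carcinoma and carcinoma in situ (n = 6 each) share the code letter C, and no gene separated them at the adjusted threshold. The smallest adjusted p was 0.434; edgeR, DESeq2 and limma-voom each called 0 genes, and 1259 genes (7.14%) had an unadjusted p under 0.05 in edgeR. Zfp36, which destabilises cytokine transcripts (GRCm38 chromosome 7, 28376784 to 28380253), was 78.9 ± 14.99 CPM in invasive carcinoma and 59.4 ± 5.28 in carcinoma in situ (log2 0.41 ± 0.11, adjusted p = 0.487, 4 of 6 above every carcinoma in situ). The immediate early transcription factor Fos was 49.1 ± 41.3 against 22.4 ± 6.76 CPM (1.13 ± 0.33, adjusted p = 0.605, 3 of 6), and the late envelope gene Lce3d 119 ± 44.9 against 58.7 ± 26.6 (1.02 ± 0.31, 0.623, 4 of 6). Pdgfra, a fibroblast receptor, was 23.8 ± 6.36 against 33.9 ± 4.16 CPM (-0.51 ± 0.15, adjusted p = 0.605, 5 of 6 below). Of 43 lists camera called 18, with 0 members called over all genes, and with an estimated correlation and by fry 0 lists were called. The lowest camera adjusted p values were for fibroblast and collagen genes (median -0.36, 2.1e-10, 3 lower adjusted over the list alone) and for cornified envelope genes (median 0.50, 3.0e-10, 0 adjusted over the list alone), each 0.428 with an estimated correlation. Immediate early genes had 5 of 22 higher adjusted over the list alone (median 0.24, camera adjusted p = 3.1e-06, 0.428 with an estimated correlation). In simulated data of this size 53.7% of 1.5-fold and 85.1% of 2-fold changes were recovered. Power in the real samples may be lower.

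Invasive carcinoma (n = 6) had far lower type I interferon transcripts than hyperplasia (n = 8) and far higher neutrophil attractant and collagenase transcripts. Isg15 fell from 52.4 ± 13.6 to 7.09 ± 3.69 CPM (log2 -2.88 ± 0.38, adjusted p = 9.8e-06), and Ifi27l2a, another interferon-induced gene, from 82.7 ± 24.95 to 21.3 ± 4.91 (-1.96 ± 0.25, 5.5e-06). Mmp13 rose from 0.628 ± 0.294 to 27.6 ± 32.0 CPM (5.46 ± 0.86, adjusted p = 6.2e-05), and Cxcl1 from 0.611 ± 0.350 to 11.5 ± 8.92 (4.24 ± 0.58, 1.3e-05). In all 4 genes the 6 carcinomas lay beyond every hyperplasia sample. The interferon list fell in 24 of 25 members and 25 adjusted over the list alone (median -1.97, camera adjusted p = 1.2e-19). The IL-17 and acute inflammatory cytokine list rose in 23 of 24 both ways (median 3.13, 3.2e-11), and neutrophil genes rose in 17 of 18 both ways (median 3.68, 7.0e-08), all 3 lists with an adjusted p of 0.29 with an estimated correlation. MHC class I genes fell in 12 of 16 both ways (median -0.55, camera adjusted p = 4.4e-06, 0.436 with an estimated correlation). The p53 target list fell in 8 of 22 and rose in 1, 9 and 2 adjusted over the list alone (median -0.17, camera adjusted p = 0.026, 0.408 with an estimated correlation), and was not called without invasive carcinoma samples C03 (adjusted p = 0.0778) or C05 (0.0792).

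Ribosomal protein genes rose in 32 of 32 both ways (median 0.51, camera adjusted p = 3.5e-16, 0.399 with an estimated correlation), among them Rpl3, from 507 ± 36.9 to 771 ± 138 CPM (log2 0.60 ± 0.10, adjusted p = 5.2e-05, 6 of 6). Invasion proteases and laminin receptors rose in 17 of 21 and fell in 3, 18 and 3 adjusted over the list alone (median 1.29, camera adjusted p = 2.5e-05, 0.436 with an estimated correlation). Basal keratinocyte genes rose in 10 of 15, 11 adjusted over the list alone (median 0.81, camera adjusted p = 4.6e-06, 0.29 with an estimated correlation). Hypoxia and glycolysis genes rose in 14 of 22 and fell in 1, 15 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 3.6e-04, 0.436 with an estimated correlation), with the carbonic anhydrase Car12 at 245 ± 74.2 against 124 ± 11.3 CPM (0.98 ± 0.13, adjusted p = 6.1e-06, 6 of 6). Among driver genes of oral squamous carcinoma, Trp63, the master regulator of squamous epithelium, rose by 0.74 ± 0.13 (adjusted p = 1.1e-04, 6 of 6) and Notch1, a differentiation receptor, fell by 0.55 ± 0.12 (9.3e-04, 4 of 6). Endothelial genes fell in 14 of 15 both ways (median -0.67, camera adjusted p = 2.5e-08), and nerve and Schwann cell genes in 9 of 13, 10 adjusted over the list alone (median -0.97, 2.4e-06), each with an adjusted p of 0.29 with an estimated correlation. Skeletal muscle genes fell in 21 of 32, 25 adjusted over the list alone (median -0.48, camera adjusted p = 7.0e-08, 0.522 with an estimated correlation). With their own score as a covariate the median of 0.10 is uninformative.

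Csn1s1 rose from 0.243 ± 0.309 CPM in hyperplasia to 22.01 ± 26.8 in invasive carcinoma (log2 6.501 ± 0.93, adjusted p = 3.0e-05, 6 of 6), by 7.13 without hyperplasia sample A05 and by 5.55 without invasive carcinoma sample C12. S100a9 rose from 154 ± 272 to 2380 ± 1428 CPM (3.96 ± 0.86, adjusted p = 0.00114, 5 of 6), and by 5.27 without hyperplasia sample A05. Apol9a and Apol9b, which may share reads, fell by 3.68 ± 0.41 and 3.08 ± 0.36 (adjusted p = 7.2e-07 and 1.5e-06, 6 of 6), and Oas3, an antiviral nucleotide synthetase, by 2.61 ± 0.45 (1.3e-04, 6 of 6). The test in edgeR called 3376 genes higher and 3392 lower, 470 and 485 of them at least 2-fold, with 8303 at an unadjusted p under 0.05. With the muscle score as a covariate 1458 were called. The share that was higher was 49.9%, but 51.3% with RLE factors. Of 43 lists camera called 21, and 0 with an estimated correlation.

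Of the 22 tested immune checkpoint genes, 10 to 14 rose against normal tissue depending on the stage. Cd274, which encodes the ligand PD-L1 (GRCm38 chromosome 19, 29367455 to 29388095, ENSMUSG00000016496.7), was 5.36 ± 0.682 CPM in normal tissue, 12.1 ± 2.14 in hyperplasia, 11.3 ± 8.74 in dysplasia, 9.90 ± 1.99 in carcinoma in situ and 10.3 ± 2.89 in invasive carcinoma. Against normal tissue it rose by log2 1.17 ± 0.36 in hyperplasia (adjusted p = 0.0309, 8 of 8), 1.07 ± 0.37 in dysplasia (0.0322, 7 of 7) and 0.94 ± 0.37 in invasive carcinoma (0.0401, 5 of 6), and was 0.88 ± 0.37 higher in carcinoma in situ (0.0617, 6 of 6). These calls were lost without any single normal sample: without D01, D02 and D03 the adjusted p was 0.0948, 0.127 and 0.066 in hyperplasia, 0.0976, 0.119 and 0.0632 in dysplasia and 0.116, 0.0945 and 0.0654 in invasive carcinoma. In dysplasia the rise was 0.59 without B02 (adjusted p = 0.0574), and in invasive carcinoma the adjusted p was 0.0535, 0.0521, 0.0736 and 0.0617 without C03, C05, C06 and C09. Between lesion stages Cd274 differed by -0.10 ± 0.26 from hyperplasia to dysplasia (adjusted p = 0.868), -0.19 ± 0.28 on to carcinoma in situ (0.718) and 0.06 ± 0.29 on to invasive carcinoma (0.973), and by -0.23 ± 0.27 between hyperplasia and invasive carcinoma (0.526). Without dysplasia sample B02 the value from hyperplasia to dysplasia was -0.58 (adjusted p = 0.0425) and that from dysplasia to carcinoma in situ turned to 0.30 (0.348).

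Pdcd1, the PD-1 receptor gene (GRCm38 chromosome 1, 94038305 to 94052553), was 0.0368 ± 0.0319 CPM in normal tissue, under the 3-count floor of 0.0509, and 0.676 ± 0.226 in hyperplasia, 0.996 ± 0.539 in dysplasia, 1.63 ± 0.748 in carcinoma in situ and 1.89 ± 0.378 in invasive carcinoma. Its log2 rise over normal tissue was 4.10 ± 0.73, 4.66 ± 0.71, 5.36 ± 0.70 and 5.58 ± 0.69 in turn (adjusted p = 3.9e-04, 1.3e-04, 8.4e-06 and 2.4e-06), in every lesion sample, and 3.47, 4.04, 4.75 and 4.97 without D03. From hyperplasia to invasive carcinoma it rose by 1.48 ± 0.31 (adjusted p = 6.4e-04, 6 of 6). Ctla4, the inhibitory receptor of activated T cells (GRCm38 chromosome 1, 60887000 to 60915832), was 0.434 ± 0.0816 CPM in normal tissue and rose by 2.39 ± 0.42 in hyperplasia (adjusted p = 4.0e-04, 8 of 8), 1.65 ± 0.43 in carcinoma in situ (0.00406, 6 of 6) and 1.98 ± 0.43 in invasive carcinoma (6.0e-04, 6 of 6). In dysplasia its rise of 1.25 ± 0.43 (adjusted p = 0.0312, 6 of 7) was lost without D01 (0.0894), D02 (0.131), D03 (0.0557), B02 (0.0522), B03 (0.057) or B05 (0.0527). From hyperplasia to dysplasia Ctla4 fell by 1.14 ± 0.27 (adjusted p = 0.012, 4 of 7). The checkpoint list rose in 12 of 22 members in hyperplasia (13 adjusted over the list alone), 10 in dysplasia (12, with 1 falling), 13 in carcinoma in situ (14) and 14 in invasive carcinoma with 1 falling both ways. Its median was 0.93, 0.59, 0.81 and 0.95, with camera adjusted p = 3.0e-06, 0.0144, 1.7e-04 and 5.6e-04, and p = 0.145, 0.499, 0.329 and 0.33 with an estimated correlation. The call in dysplasia was lost without B01 (adjusted p = 0.0534).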

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

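The tests of the interferon pattern, the oxidative phosphorylation pattern and the random splits were chosen after those results were seen, and the bone marrow test before. Among 440 groups of values examined (65 named genes, 43 list scores, total counts and the mitochondrial percent within each stage of 6 to 8 samples), 43 held 1 sample far from the others by Dixon's criterion, and chance gives about 1 in 20 groups. These fell in 13 samples, with 11 in B01 and 8 in A05. Gene values below are CPM and list scores mean log2 CPM, each with the range of the other samples of the stage.

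Dysplasia had lower type I interferon transcripts than hyperplasia, with a median log2 of -1.26 over the 25 genes. A larger share of immune cells in hyperplasia stays open. The 61 immune markers fell less (median -0.269, 25th percentile -0.489), but regulatory T cell Foxp3 did not (-1.38). Another share of muscle or salivary gland is argued against as the whole cause, since with both scores as covariates the median was -1.108 (quartiles -1.246 and -0.766) and 17 of 25 genes still fell. A library or collection batch marked by the code letters cannot be told apart from stage (0 hyperplasia samples with another letter). A biological change between these stages also stays open and was not tested.

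Oxidative phosphorylation transcripts were lower in invasive carcinoma than in normal tissue, by -0.632 in mean score. A smaller share of skeletal muscle is a candidate. The slope of this score on the muscle score within groups, 0.58 ± 0.046, times the muscle difference of -0.938 gives -0.544 ± 0.044, or 86.2% of the difference (SE 6.89, slope only). The slope was 0.471 in hyperplasia, 0.422 in dysplasia, 0.604 in carcinoma in situ and 0.73 in invasive carcinoma. A few genes taking most of the counts would shift all other genes alike, and is argued against, since the 75th percentile of the list lay at -0.565 relative to the median of all tested genes. The slope cannot tell less muscle from a lower level per cell, which stays open, untested.

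Slc4a1 was far higher in normal sample D01 (53.3 CPM, 983 counts), dysplasia sample B01 (20.8 CPM [others 0.0446 to 0.133], 477 counts) and invasive carcinoma sample C12 (3.4 CPM [0.0356 to 0.106], 72 counts) than in the rest of their groups. Bone marrow in the tissue is a candidate source: of 8 progenitor genes, 6 in D01, 6 in B01 and 4 in C12 were at least 3 times the next sample of the group, so the fewest was 4. Mpo was 2.93 CPM in D01, 3.80 in B01 and 6.53 in C12, where Elane was 2.93 against at most 0.044 in the other invasive carcinomas. Bone marrow and another source of these transcripts cannot be told apart for these samples with levels this low, and no biological explanation was tested.

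The random splits were 50 per comparison, with the true grouping included and only the 2 groups in the fit. For each lesion stage against normal tissue, 1 of 50 splits gave as many genes, the true one, which is the lowest share possible. In stage order the true split had 3231, 4493, 4611 and 5640 genes, the others at most 552, 1311, 30 and 98. The same held for dysplasia against hyperplasia (1 of 50, 2057 genes, others at most 0), carcinoma in situ against dysplasia (1 of 50, 200 genes, others at most 0) and invasive carcinoma against hyperplasia (1 of 50, 6277 genes, others at most 2932). For invasive carcinoma against carcinoma in situ the true split gave 0 genes, so 50 of 50 had to give as many (others at most 48), and nothing follows about chance.

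Hyperplasia sample A05 was low in interferon-induced genes. Its values were 10.1 for Apol9a [18.7 to 25.3], 7.55 for Apol9b [12.7 to 16.5], 7.78 for Ifi44 [16.8 to 24.5], 25.9 for Isg15 [41.6 to 63.7], 10.0 for Oas3 [17.4 to 26.6] and 30.5 for Oasl2 [63.8 to 84.0]. Its type I interferon score was 3.41 [4.10 to 4.43], and its Mmp3 was high at 7.78 [3.67 to 4.86]. Sample A07 had the lowest Spp1, 1.76 [3.03 to 4.38]. Sample A08 had Crisp3 at 2.65 [0.079 to 0.301], Klk1b9 at 1.03 [0 to 0.162], Krtap4-6 at 0.049 [1.06 to 6.81] and an adipocyte score of 3.28 [1.20 to 1.86].

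Dysplasia sample B01 had Spp1 at 10.8 [1.96 to 3.20] and Tchh at 1020.0 [1890 to 2930]. Its scores were 2.18 for B and plasma cells [0.19 to 0.49], 3.59 for adipocytes [1.08 to 2.08], 5.53 for erythrocytes [1.84 to 2.90], 5.80 for fibroblasts and collagen [5.23 to 5.38], 2.78 for neutrophils [0 to 1.02] and 6.16 for vascular smooth muscle and pericytes [4.86 to 5.41]. Its injury keratin score was 6.25 [6.53 to 6.74] and its suprabasal score 8.22 [8.87 to 9.16]. Sample B02 had Csn1s1 at 6.64 [0.393 to 1.34] and Ifi27l2a at 55.6 [21.4 to 31.9]. Sample B05 had Duox2 at 55.1 [2.60 to 3.71], Fxyd2 at 18.1 [0.937 to 2.04] and Klk1b9 at 1.30 [0 to 0.089]. Sample B06 had Klk6 at 85.0 [7.10 to 16.3], Angptl4 at 1.66 [3.76 to 6.09], a mitochondrially encoded score of 7.26 [7.81 to 8.21] and 5.95% mitochondrial counts [7.20 to 7.98].

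Carcinoma in situ sample C01 had 27.9 M counts [22.5 to 23.5], and C02 had Igsf9b at 1.10 [2.68 to 4.02]. Among invasive carcinomas, C03 had a cytotoxic lymphocyte score of 0.34 [-1.23 to -0.80], C05 Fam107a at 7.58 [2.65 to 3.71], and C08 an EMT regulator score of 3.0 [3.26 to 3.33]. Sample C12 had scores of 1.80 for B and plasma cells [0.24 to 0.70], 4.12 for erythrocytes [1.51 to 2.14], 7.60 for oxidative phosphorylation [8.13 to 8.43] and 8.55 for skeletal muscle [9.33 to 9.73].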

How the results depend on the processing

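The salivary gland covariate, both covariates together, leave-one-out for the lists and leaving out D01, B01 and C12 were chosen after the data were seen. Over the alternatives run gene by gene, which leave out the adjusted p under 0.01, named genes kept direction and side of the threshold in 6599 cases, fell short of it in 594, newly passed it in 6 and reversed in 14; over RLE and upper-quartile factors, the single covariates, an estimated correlation and leave-one-out, called lists kept both in 2940, fell short in 331 and reversed in 10. With RLE and upper-quartile factors the gene counts of all 8 comparisons stayed within 1.5 times those reported, and no scaling moved the median of all genes by over 0.1 log2. The counts against normal tissue depend on 3 samples, and most on D02. No replicate block by code number could be fitted for invasive carcinoma against carcinoma in situ (no shared number) or normal tissue (1 shared). Whether the numbers pair the samples stays open: same-number correlations ran from -0.564 to 0.512. Where a reason follows from the setting (a stricter threshold, fewer samples) it is that setting; for the other changes below the cause was not tested. Depth limits genes near 1 CPM such as Pdcd1, where 1 CPM is about 18 to 28 counts.

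An adjusted p under 0.01 left 987 genes in hyperplasia, 2004 in dysplasia and 3972 in carcinoma in situ against normal tissue, 301 in dysplasia against hyperplasia, 62 in carcinoma in situ against dysplasia and 4009 in invasive carcinoma against hyperplasia, with 775 shared calls of hyperplasia and invasive carcinoma against normal tissue. glmTreat against a fold of 1.5 left 262, 155, 748 and 1359 genes in the 4 stages against normal tissue, 28 in dysplasia against hyperplasia, 0 in carcinoma in situ against dysplasia (964 in edgeR, 4112 at an unadjusted p under 0.05, 1520 in DESeq2 and 2241 in limma-voom) and 407 in invasive carcinoma against hyperplasia, with 187 shared calls. limma-voom called 4606 in hyperplasia and 6831 in dysplasia against normal tissue, 3584 in dysplasia against hyperplasia and 2241 in carcinoma in situ against dysplasia, with 3543 shared calls, and turned Cd274 in carcinoma in situ against dysplasia to 0.10. Without an expression filter 473 genes were called in dysplasia against hyperplasia and 327 in carcinoma in situ against dysplasia, and with only the 2 groups in the fit 2057 and 200.

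With the skeletal muscle score as a covariate 768 genes were called in dysplasia, 2023 in carcinoma in situ and 1434 in invasive carcinoma against normal tissue, 589 in dysplasia against hyperplasia, 1886 in carcinoma in situ against dysplasia and 1458 in invasive carcinoma against hyperplasia, with 744 shared calls. Camera then called 17 lists in dysplasia against hyperplasia. Among list medians, basal keratinocyte in dysplasia against normal tissue went from 0.54 to 0.017. The type I interferon median in invasive carcinoma against normal tissue turned to 0.24. In dysplasia against hyperplasia and invasive carcinoma against carcinoma in situ and hyperplasia, oxidative phosphorylation turned to 0.052, 0.049 and 0.08. Skeletal muscle gave 0.069, 0.055 and 0.10, uninformative as the covariate is its own score. Cd274 turned to 0.16 in dysplasia and 0.27 in invasive carcinoma against hyperplasia. With the salivary and muscle scores together, 888, 2292 and 1722 genes were called in dysplasia, carcinoma in situ and invasive carcinoma against normal tissue, 2056 in carcinoma in situ against dysplasia and 1751 in invasive carcinoma against hyperplasia, with 874 shared calls, and Cd274 turned to 0.19 in dysplasia and 0.28 in invasive carcinoma against hyperplasia. Without D01, B01 and C12, Igha turned to 0.61 in hyperplasia against normal tissue, and 2129 genes were called in dysplasia against hyperplasia and 1556 in carcinoma in situ against dysplasia.

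The replicate block called 756 genes in hyperplasia (1013 in the same samples unblocked), 162 in dysplasia (285) and 10 in carcinoma in situ (71) against normal tissue, 2718 in dysplasia against hyperplasia (2042), 0 in carcinoma in situ against dysplasia (0) and 195 in invasive carcinoma against hyperplasia (713), and turned Cd274 in the last to 0.067. With an estimated correlation camera called 0 lists in 7 comparisons and 1, the p53 targets, in dysplasia against hyperplasia. fry called 16 lists in hyperplasia against normal tissue, 8 in dysplasia against hyperplasia, 3 in carcinoma in situ against dysplasia and 0 in invasive carcinoma against carcinoma in situ, where camera called 18.

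Leaving out 1 sample gave 926 (D02) to 2876 (A04) genes in hyperplasia, 1282 (D02) to 5308 (B01) in dysplasia and 4238 (D02) to 7306 (C04) in carcinoma in situ against normal tissue, with 755 (D02) to 2376 (A04) shared calls. It gave 507 (A04) to 1486 (B01) in dysplasia against hyperplasia, 164 (C07) to 2201 (C04) in carcinoma in situ against dysplasia, and 0 to 1 in invasive carcinoma against carcinoma in situ, the 1 without C03 or C07. Slc4a1, invasive carcinoma vs normal, ran from -5.41 (D02) to 1.87 (D01), and Igha in hyperplasia against normal tissue from -4.96 (D03) to 0.61 (D01). Cd274 ran from -0.58 (B02) to 0.014 (B06) in dysplasia against hyperplasia, from -0.30 (B06) to 0.30 (B02) in carcinoma in situ against dysplasia, and from -0.036 (C06) to 0.20 (C12) in invasive carcinoma against carcinoma in situ. In that last comparison the oxidative phosphorylation median ran from -0.13 (C05) to 0.014 (C12) and the NRF2 median from -0.33 (C04) to 0.087 (C02).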

Other observations

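The interferon and p53 correlation was chosen as a test before its result was seen. The 5 clock genes below were picked after their values were seen, with other clock genes not shown and no group tested. Per2, a core repressor of the clock (GRCm38 chromosome 1, 91415982 to 91459324), was 8.15 CPM in normal tissue (n = 3), 7.91 in hyperplasia (n = 8), 17.3 in dysplasia (n = 7), 7.58 in carcinoma in situ (n = 6) and 9.40 in invasive carcinoma (n = 6). It rose from hyperplasia to dysplasia by log2 1.13 ± 0.21 (edgeR adjusted p = 0.00149) and fell on to carcinoma in situ (-1.19 ± 0.23, 0.00832, 5 of 6 below every dysplasia sample). In invasive carcinoma against normal tissue the clock output genes Dbp and Tef fell by 1.51 ± 0.38 and 1.18 ± 0.15 (adjusted p = 0.00224 and 2.4e-06), and the nuclear receptors Nr1d1 and Nr1d2 by 1.20 ± 0.26 and 0.84 ± 0.13 (5.3e-04 and 3.2e-05). The labels give no time of day of collection.

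Type I interferon and p53 target scores were both highest in hyperplasia, at 4.17 and 5.21 log2 CPM on average. The hypothesis that samples with more interferon have more p53 target transcripts was tested over the 27 lesion samples with scores centred by stage. Pearson's r was -0.712 (p = 3.4e-04) and Spearman's rho -0.651 (p = 0.00193) in a two-sided test of 100000 permutations, and r was -0.640 without the 2 samples farthest from the median, B02 and C12. The lists share 0 genes, and the sign opposed the hypothesis in the 1 such relation computed. Muscle share was not adjusted for and may move both scores.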
